A study of Mus musculus with 2 samples.

How the data were processed

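Single nuclei of the spinal dynorphin lineage were profiled by droplet sequencing (10x Genomics 3' v3 chemistry). The nuclei carried a green fluorescent nuclear-envelope reporter switched on by Cre recombinase under control of the prodynorphin gene (Pdyn), and were sorted on that fluorescence from the dorsal part of the lumbar cord (L3-L5). Each of the 2 libraries pooled 8 adult mice of either sex: a naive pool, exposed only to isoflurane at postnatal day 3, and an injured pool, with an incision of the left hindpaw at postnatal day 3. Per the labels, Cell Ranger 3.0.2 and Seurat (version not stated) were used with genome build mm10; the gene annotation, the use of intronic reads and the filters on nuclei are not given in the sources used here.

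The deposited matrix held raw UMI counts for 19575 genes in 7610 nuclei. The normalized values deposited by the authors were the natural log of 1 plus 10000 times the count over the total of the nucleus, with a largest deviation of 6e-15 from that formula. As the values show, each listed gene had a count in at least 4 nuclei, and each nucleus had at least 514 genes. All deposited nuclei were used, with no further filter. The raw counts served for all main values, and the deposited normalized values only for an alternative. Naive nuclei held 30602222 UMIs in total (median 6955 per nucleus) and injured nuclei 32934588 (median 8464), a ratio of medians of 1.22. A count of 0 in a whole library allows a level of up to 3 counts, 0.0980 CPM (UMIs scaled to a total of 1000000) in the naive and 0.0911 CPM in the injured library.

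No annotation of nuclei was among the files used, so classes were rebuilt and may differ from those of the study. Nuclei of both libraries were clustered together in scanpy 1.11.5 (anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, umap-learn 0.5.12), without batch correction. Counts were scaled to 10000 per nucleus and log-transformed. The steps used 2000 variable genes, values clipped at 10, 30 principal components, 15 neighbours and a Leiden resolution of 1.0, with seed 0. Neuropeptides, peptide receptors, immediate early, heat shock, mitochondrially encoded, Y-linked and X-inactivation genes, 104 in the table, were kept out of the variable genes. Names came from marker genes fixed in advance, and carry the suffix "-like". A name needed at least 3 detected markers, a neuron class was set by its transmitter genes (Gad1, Gad2, Slc32a1 and Slc6a5 against Slc17a6), and a cluster stayed unnamed when it carried neuron markers beside those of glia or Schwann cells, or more markers of another class than of its own among its 10 leading genes. Cluster 22 was named astrocyte-like by its higher score (4.72), although its ependymal score was 4.27. The thresholds of that rule, an inhibitory to excitatory ratio of at least 10 and an excitatory to inhibitory ratio of at least 4, were set after the data had been seen. Clusters 3 and 15, whose nuclei held both kinds of marker, were clustered again and named by part.

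Doublets were not removed in the main setting. Scrublet (in scanpy, with scikit-image 0.26.0) called 106 of 4063 naive nuclei (2.61%) and 7 of 3547 injured nuclei (0.197%) doublets, at automatic thresholds of 0.236 and 0.493. In the injured library it therefore did not work, and its removal stands only as an alternative. Because the pools held both sexes, nuclei with both Xist and Y-linked UMIs (Ddx3y, Eif2s3y, Kdm5d, Uty) gave a second view of doublets and free RNA.

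With 1 pooled library per group there was no test between groups, and no p-value, standard error or count of changed genes was made from nuclei. Raw counts of a class were summed per library and scaled to CPM by the class total. Each level has an exact Poisson interval, each share of nuclei an exact Clopper-Pearson interval, and each ratio of injured over naive CPM an exact conditional binomial interval, all at 95%. These intervals cover counting error only, not variation between mice. For levels and ratios they also leave out the sampling of nuclei that differ from each other. Genes and gene lists were compared only in classes with at least 100 nuclei in each library. In smaller classes, the shares of nuclei, the levels of single peptides and receptors and the summed counts of 5 lists were set side by side. Named genes were the 12 highest and 12 lowest ratios among genes with at least 100 UMIs in the class over both libraries and a UMI in at least 5% of its nuclei in 1 library. They also had to have the same direction in nuclei with only Xist UMIs and in nuclei with only Y-linked UMIs, which come from different mice of each pool. Predicted genes (Gm and Rik symbols, accession-like symbols), mitochondrial, Rpl and Rps, Y-linked and X-inactivation genes were left out of that ranking. From each list the 2 highest and 2 lowest members with at least 100 UMIs could be named. The gene lists, the markers, the naming rule for genes and the alternative settings, except those named as chosen later, were chosen before the data were examined.

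The gene lists were neuropeptides, neuropeptide receptors, GABA and glycine receptors, ionotropic and metabotropic glutamate receptors, sodium channels, potassium and HCN channels, calcium channels, presynaptic release, postsynaptic scaffolds, axon guidance, neuronal adhesion, neurotrophin signalling and axon regeneration, chromatin and DNA methylation, immediate early genes, heat shock, inflammatory signalling, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, Y-linked and X-inactivation genes. Marker lists of astrocytes, oligodendrocytes, their precursors, microglia, endothelial cells, mural cells, meningeal fibroblasts, ependymal cells, Schwann cells and lymphocytes were run alongside. A list's median log2 ratio was taken over members with at least 20 UMIs in the class. It was placed by percentile among 10000 random lists of the same size, matched on expression in 20 bins. A percentile under 2.5 or over 97.5 is called outside the middle of random lists; it describes these 2 libraries and is not a test between groups. On simulated counts with known differences, the sign was right in 100% of genes given a 1.5-fold or 2-fold difference. The intervals held the true ratio in 94% to 95.3% of genes, and 5% of unchanged lists fell outside 2.5 to 97.5.

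Gene coordinates and lengths came from GENCODE vM21 on mm10, matched by symbol for 18777 of 19575 genes (95.9%); that release is an assumption, since the annotation used for counting is not stated. Lists were also placed among random lists matched on gene length, drawn from the 100 genes nearest in length within 10 expression bins. A coarser match was made finer after its results had been seen, because simulated data showed it to be biased; no percentile crossed 2.5 or 97.5 between both versions. In 40 simulations of a length trend alone, the finer match placed 2.5% to 15% of unaffected lists outside the middle 95%, so its percentiles are somewhat too extreme. All lists given an added log2 difference of -0.3 were found. These simulations gave every gene independent noise of the same size, whatever its number of UMIs, so they can overstate what the match finds here.

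Alternatives were trimmed mean of M-values (TMM) factors from edgeR 4.0.16 in R 4.3.3, used for scaling factors only, and median-of-ratios factors. Others were minimums of 20, 100 or 500 UMIs, equal weight of nuclei or of clusters, the deposited normalized values, either sex-marker set alone, thinning of each nucleus to 4000 UMIs, removal of Scrublet doublets, and removal of the 10% of nuclei with most UMIs. Thinning left out 247 naive and 141 injured nuclei that were shallower. Class shares were also computed at resolutions 0.5 and 2.0, with 1000 variable genes and 20 components or 4000 and 50, centred by library, without doublets, with at least 1000 UMIs, and from each nucleus's own markers. Further alternatives were chosen after seeing the data: adding unnamed neuron clusters, leaving out nuclei with both sex markers, and leaving out cluster 23. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.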

Results

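Nuclear RNA was measured in single GFP-sorted nuclei of the Pdyn lineage, cells that expressed prodynorphin, the precursor of the opioid peptide dynorphin, at some time in life. The nuclei came from lumbar dorsal spinal cord of adult mice. The naive library held 4063 nuclei and the injured library 3547, each from a pool of 8 mice, with totals of 30602222 and 32934588 UMIs. The median depth was 6955 UMIs per naive and 8464 per injured nucleus. The design asks which transcripts differ in adult dynorphin-lineage cells after an incision in the first days of life, and which kinds of neuron the lineage contains. Each group had 1 pooled library, so no difference between groups has a replicate check, and all intervals (95%) cover counting error only.

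Most nuclei of both libraries were inhibitory-like neurons, which carried the GABA and glycine genes Gad1, Gad2, Slc32a1 and Slc6a5. They made up 2584 naive nuclei (63.6%, 62.1 to 65.1) and 2191 injured nuclei (61.8%, 60.1 to 63.4). Excitatory-like neurons, marked by the vesicular glutamate transporter Slc17a6, made up 887 naive (21.8%, 20.6 to 23.1) and 772 injured nuclei (21.8%, 20.4 to 23.2). Of the inhibitory-like and excitatory-like nuclei together, the excitatory-like part was 25.6% in the naive and 26.1% in the injured library. Neurons like those that contact the cerebrospinal fluid (CSF), marked by the channel gene Pkd2l1, made up 106 naive (2.61%, 2.14 to 3.15) and 48 injured nuclei (1.35%, 0.999 to 1.79); this fall lay in nuclei with Xist UMIs (3.62% and 1.32%), while in those with Y-linked UMIs the share rose from 0.47% to 1.5%. Astrocyte-like nuclei, which also carried ependymal markers, numbered 52 and 47, oligodendrocyte-like nuclei 42 and 45, and microglia-like nuclei 8 and 3. Unnamed nuclei were 9.45% of the naive and 12.4% of the injured library. Among them, unnamed parts of the neuron clusters 3, 14 and 15 held 335 naive (8.25%) and 336 injured nuclei (9.47%), kept out because they held both inhibitory and excitatory markers, had under 3 detected markers of their class, or, as cluster 14 and a part of cluster 15, had more markers of another class among their 10 leading genes. Cluster 14, with 123 naive and 88 injured nuclei, held inhibitory transmitter genes at 1085 CPM against 5.53 CPM of excitatory ones. The inhibitory-like shares leave it out. A GFP gate set the population, the depth differed between libraries, and doublets were not removed, all of which can shift the shares of all classes. With each nucleus classed by its own markers instead, the excitatory-like share was 17.5% in the naive and 19.0% in the injured library.

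In inhibitory-like neurons, the injured library had higher levels of Alk, a receptor tyrosine kinase, and of Zfpm2, a cofactor of GATA transcription factors. It had lower levels of Rnd2 and of Rplp0, a protein of the ribosomal stalk whose symbol falls outside the ribosomal list. Alk (ENSMUSG00000055471, mm10 chromosome 17, 71868972 to 72604627) was at 289.1 CPM in the naive and 521.7 CPM in the injured library, a ratio of 1.81 (1.75 to 1.87). Zfpm2 (ENSMUSG00000022306, chromosome 15, 40655035 to 41104592) was at 14 and 28 CPM, a ratio of 2.03 (1.74 to 2.36). Rnd2 (ENSMUSG00000001313, chromosome 11, 101464999 to 101471853) was at 9.32 and 4.14 CPM, a ratio of 0.445 (0.335 to 0.585). Rplp0 (ENSMUSG00000067274, chromosome 5, 115559467 to 115563727) had a ratio of 0.501 (0.391 to 0.639).

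Much of the Alk difference in this class lay in 1 small cluster. Cluster 23 held 29 naive and 62 injured nuclei, with Alk at 6562 CPM (6201 to 6937) and 9696 CPM (9423 to 9975). It carried 1239 of the 5276 naive and 4771 of the 9698 injured Alk UMIs of the class. Alk, Plekhg1 and Entpd1 are among the 10 genes that define cluster 23, so its numbers of nuclei are not read as a difference between libraries. In other inhibitory-like clusters, looked at after the data were seen, Alk was also higher in the injured library with counting intervals that did not overlap: 245.6 and 475.3 CPM in cluster 2, 235.9 and 374.8 in cluster 6, 10.7 and 44.1 in cluster 7, 472.6 and 583.1 in cluster 5, and 550.7 and 650.2 in cluster 8. The intervals overlapped in cluster 1, the largest of this class (100.5 and 90.9 CPM), and in clusters 10 (122.9 and 115.4), 11 (19.6 and 19.2), 12 (42.0 and 50.1) and 13 (63.8 and 79.8). In oligodendrocyte-like nuclei Alk was at 48.0 CPM (15.6 to 112.1) and 86.6 CPM (44.7 to 151.2), on 5 and 12 UMIs. In astrocyte-like nuclei it was at 35.7 CPM (11.6 to 83.4) and 186.7 CPM (137.6 to 247.5). The levels of cluster 7 do not stand above these, but these glia-like nuclei were shallower, with median depths of 2126 to 3503 UMIs. At depths nearer to those of cluster 7, cluster 11 was at 19.2 CPM (11.9 to 29.4) in the injured library. Cluster 7 lay above that, at 44.1 CPM (34.8 to 55.1). Free RNA and doublets were not tested as sources of the differences in clusters 2, 5, 6, 7 and 8. Outside cluster 23, inhibitory-like nuclei with at least 20 Alk UMIs, a limit chosen after seeing the data, numbered 17 naive and 34 injured. They held 14.5% and 27.3% of the Alk UMIs there. The remaining nuclei, 2538 naive and 2095 injured, were at 192.6 and 201.9 CPM. This split uses Alk itself and injured nuclei were deeper. It describes where the UMIs lay and does not test whether the remaining nuclei differed. Without cluster 23, a setting chosen after seeing the data, the log2 ratio of Alk was 0.28 in place of 0.85. That of Plekhg1, a guanine nucleotide exchange factor, was 0.34 in place of 0.75, and that of Entpd1, an enzyme that breaks down extracellular ATP, was 0.16 in place of 0.61. The other 21 named genes of this class kept log2 ratios within their counting intervals without cluster 23.

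Further named genes with a higher ratio in inhibitory-like neurons were Cacna2d1, the calcium channel subunit bound by gabapentin (1.89, 1.55 to 2.32), Fam19a2 (1.68), Efhd1 (1.63), Myo3a (1.59), the membrane collagen gene Col25a1 (1.56), Fign (1.56), Nell1 (1.55) and Pir (1.53). Cacna2d1 had only 149 naive and 287 injured UMIs in this class, against 18746 over both libraries in excitatory-like neurons, where its log2 ratio was 0.08. Zfpm2 likewise had 2852 UMIs and a log2 ratio of 0.09 there. With the unnamed cluster 14 added, a setting chosen after seeing the data, Cacna2d1 had a log2 ratio of 0.52 and Zfpm2 of 0.74. The log2 ratio of Cacna2d1, 0.92 at the main setting, was 0.59 without the 10% of nuclei with most UMIs and 1.27 in the Xist set. Without Scrublet doublets, which over all classes were 106 naive and 7 injured nuclei, it was 1.46. Doublets and free RNA of excitatory-like nuclei were not tested as sources of the Cacna2d1 counts. With clusters given the same weight in both libraries, the log2 ratio moved beyond its counting interval for 5 named genes, to 0.50 for Alk, 0.62 for Cacna2d1, 0.31 for Fam19a2, 0.14 for Fign and 0.35 for Nell1. Named genes with a lower ratio were Tprgl (0.501), Cthrc1 (0.508), Tmem114 (0.546), Jsrp1 (0.547), the beta-tubulin gene Tubb2b (0.557), Ccdc85b (0.557), Heph, a copper-dependent ferroxidase (0.560), Tmem158 (0.562), Cdk5r2, an activator of the kinase Cdk5 (0.563), and B4galnt4 (0.576). By the naming rule, all 24 genes had the same direction in nuclei with Xist UMIs and in nuclei with Y-linked UMIs. The named genes also lie along a trend in which longer genes had higher ratios: the 12 higher ones span 46.5 to 891.7 kb and the 12 lower ones 1.71 to 15.9 kb, except Heph at 119.1 kb. Across all genes of this class the median log2 ratio was -0.22 in genes of up to 9.72 kb and 0.04 in those of at least 91.0 kb, and the named ratios are not corrected for length.

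Across 12766 genes with at least 100 UMIs in inhibitory-like neurons, the median log2 ratio was -0.08 and the middle 90% ran from -0.46 to 0.22. The SD was 0.211, against 0.136 if counting error alone were at work. That counting error leaves out the sampling of nuclei that differ from each other, which can also widen the SD. The log2 ratios in the Xist and Y-linked sets, which come from different mice of the same pools, had a Pearson r of 0.467 across 9767 genes, which are not independent replicates. Both sets of a library share its preparation and its free RNA, so this r is not a replicate check. Other ways of scaling added about 0.08 to every log2 ratio, so list medians between -0.08 and 0 are given without a direction.

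**Figure D1:**
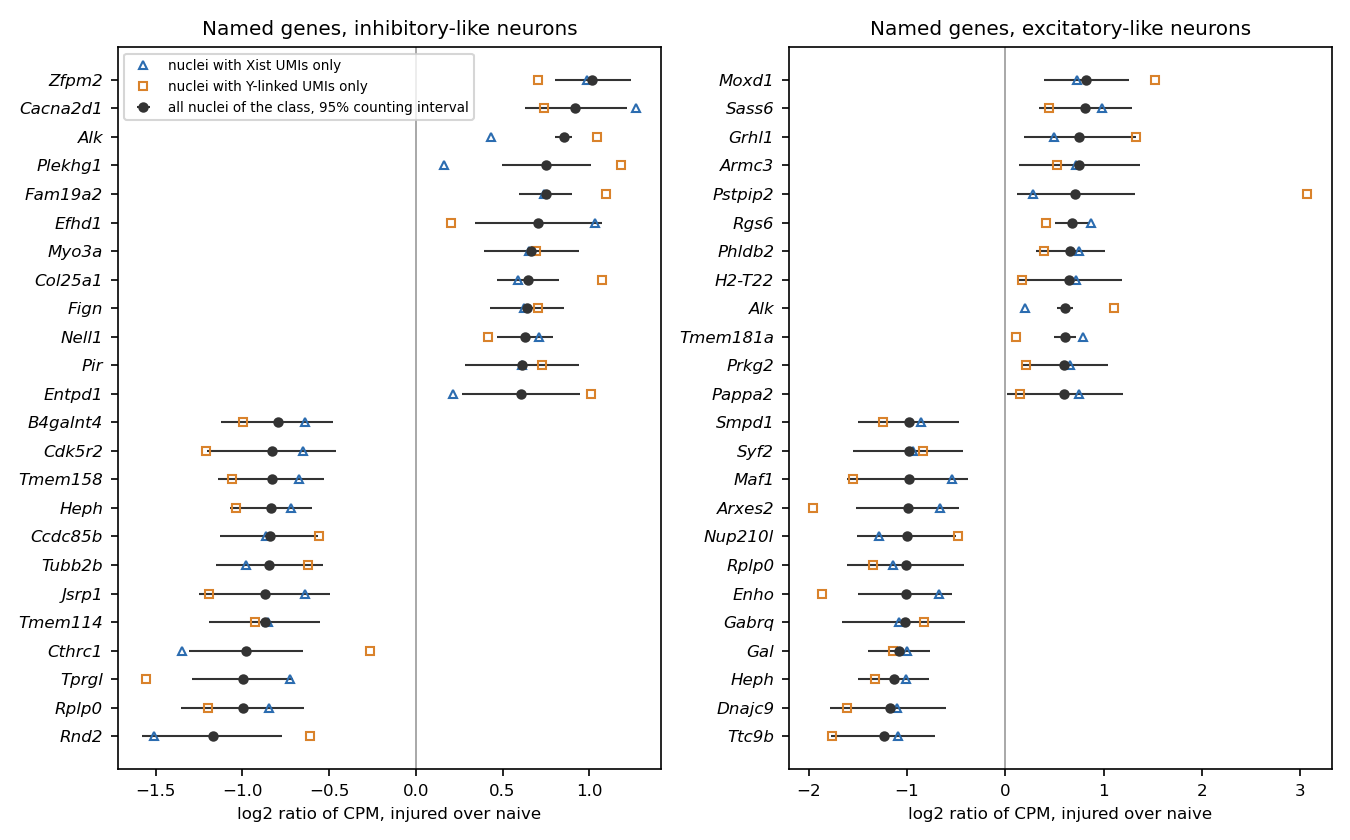
Log2 ratio of CPM, injured over naive (x axis), of the 24 named genes in inhibitory-like (left) and excitatory-like neurons (right). Black points with bars are all nuclei of the class with 95% counting intervals, triangles the nuclei with only Xist UMIs and squares those with only Y-linked UMIs; Alk lies at 0.43 in the Xist and 1.05 in the Y-linked set of inhibitory-like neurons.

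Among the fixed lists in inhibitory-like neurons, transcripts of ribosomal proteins, heat shock proteins, immediate early genes and oxidative phosphorylation had lower levels in the injured library. Receptors for GABA and glycine, axon guidance molecules and neuronal adhesion molecules had higher levels. Of 77 measured ribosomal protein genes 73 had a ratio under 1, and the median log2 ratio was -0.44 (percentile 0 of expression-matched random lists). Rps10 had a ratio of 0.57 (0.50 to 0.64). All 10 measured heat shock genes had a ratio under 1 (median -0.34, percentile 0), among them the chaperones Hspa8 (0.706, 0.654 to 0.762) and Hsp90ab1 (0.738, 0.696 to 0.781). All 16 measured immediate early genes, which respond to neuronal activity and to tissue handling, also lay under 1 (median -0.60, percentile 0), with Egr1 at 0.637 (0.481 to 0.841) and Fos at 0.858 (0.631 to 1.16). Oxidative phosphorylation genes had a median of -0.24 (percentile 0). The GABA and glycine receptor list had a median of 0.13 (percentile 100), with Gabra5 at 1.26 (1.07 to 1.48) and Gabra3 at 1.22 (1.15 to 1.29), while Gabbr1 was at 0.875. The axon guidance list had a median of 0.13 (percentile 100), led by Slit2 at 1.46 (1.37 to 1.56). The neuronal adhesion list had 0.14 (percentile 100), with the cadherins Cdh12 at 1.31 and Cdh13 at 1.29.

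Neuropeptide receptors in inhibitory-like neurons had a median of -0.22 (percentile 2.12), but lay within the middle of random lists under 8 of 15 alternatives, at percentile 25.8 in the Y-linked set. Among its members, the nociceptin receptor Oprl1 was at 0.759 and the substance P receptor Tacr1 at 1.63 (1.17 to 2.29). Neuropeptides had a median of -0.15 (percentile 18.1), which depended on the setting. It was -0.33 with nuclei given the same weight (percentile 0.09), -0.34 in the Xist set (0.03), -0.46 in the Y-linked set (0.20), -0.31 with clusters given the same weight (0.18), -0.32 without the 10% of nuclei with most UMIs (0.17) and -0.43 without cluster 23 (percentile 0). The remaining functional lists lay within the middle of random lists at the main setting: ionotropic glutamate receptors 0.04 (percentile 76.0), metabotropic glutamate receptors 0.08 (93.6), sodium channels 0.08 (95.4), potassium and HCN channels 0.02 (88.1), calcium channels -0.04 (17.9), presynaptic release 0.00 (65.6), postsynaptic scaffolds -0.04 (25.4), neurotrophin signalling and axon regeneration 0.05 (96.1), chromatin and DNA methylation -0.06 (11.8), inflammatory signalling -0.11 (41.2), mitochondrially encoded genes -0.22 (12.4) and Y-linked genes -0.09 (60.1). Among markers of other cells, the oligodendrocyte list had a median of 0.15 (percentile 99.7). The precursor list had 0.40 (percentile 99.99), measured on Lhfpl3, Tnr and Vcan, of which neurons also express Lhfpl3 (302.8 and 358.2 CPM) and Tnr (43.7 and 58.5 CPM). The endothelial list had 1.21 (percentile 100), from Mecom at 1.48 and 4.68 CPM and from Adgrl4, but was -0.39 over genes with at least 100 UMIs. The astrocyte list had -0.15 (33.7), microglia -0.09 (60.2), mural cells -0.14 (43.8), ependymal cells -0.22 (31.2) and Schwann cells 0.04 (72.7). Fewer than 3 genes of the fibroblast, lymphocyte and X-inactivation lists were measured.

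In excitatory-like neurons, the injured library had higher levels of Moxd1, a monooxygenase-like gene, of Rgs6, a regulator of G protein signalling, and of Alk. It had lower levels of the ferroxidase gene Heph and of Ttc9b. Counts of Gal, the precursor of the neuropeptide galanin, were also lower but are not separated from free RNA in this class. Moxd1 (ENSMUSG00000020000, chromosome 10, 24223517 to 24302790) was at 9.0 and 16 CPM, a ratio of 1.76 (1.31 to 2.39). Rgs6 (ENSMUSG00000021219, chromosome 12, 82588292 to 83162056) was at 58.3 and 93.3 CPM, a ratio of 1.60 (1.43 to 1.80). Gal (ENSMUSG00000024907, chromosome 19, 3409915 to 3414544) was at 32.2 and 15.3 CPM, a ratio of 0.474 (0.380 to 0.589). In oligodendrocyte-like nuclei, which should lack the gene, Gal was at 57.6 CPM (21.2 to 125.5) and 36.1 CPM (11.7 to 84.2), on 6 and 5 UMIs, so its excitatory-like ratio can follow free RNA of the inhibitory-like nuclei. Those oligodendrocyte-like nuclei had median depths of 2146.5 and 2593 UMIs, against 8112 and 9957 in excitatory-like ones. At such unlike depths, CPM cannot tell whether Gal exceeds free RNA there. Heph (ENSMUSG00000031209, chromosome X, 96455359 to 96574485) had a ratio of 0.456 (0.353 to 0.585) and Ttc9b (ENSMUSG00000007944, chromosome 7, 27653915 to 27657346) one of 0.426 (0.293 to 0.611).

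Alk in excitatory-like neurons was at 240.1 and 366.4 CPM, a ratio of 1.53 (1.44 to 1.62). Nuclei with at least 20 Alk UMIs, a limit chosen after seeing the data, numbered 5 of 887 naive (0.564%) and 19 of 772 injured (2.46%, 1.49 to 3.82). They held 8.81% of the naive and 38.2% of the injured Alk UMIs of the class. This split uses Alk itself and injured nuclei were deeper, so it describes where the UMIs lay and does not test whether the other nuclei differed. By cluster, Alk was at 231.0 CPM (214.3 to 248.6) and 560.5 CPM (533.1 to 589.0) in cluster 4, but went the other way in cluster 20, at 223.2 CPM (185.8 to 265.9) and 130.6 CPM (105.0 to 160.5). The intervals overlapped in clusters 9 (346.2 and 366.4 CPM), 16 (100.6 and 149.5), 18 (293.2 and 349.8) and 19 (115.7 and 94.0). In cluster 15, only parts of which are in this class, Alk was at 203.5 CPM (169.4 to 242.4) and 390.9 CPM (351.1 to 433.9). Without nuclei with both Xist and Y-linked UMIs, a setting chosen after seeing the data, the log2 ratio of Alk in the class was 0.50 in place of 0.61; in cluster 4 such nuclei were 5.35% (3.25 to 8.23) of the naive and 10.6% (7.16 to 14.96) of the injured ones. Doublets of nuclei with the same sex marker stay in under that setting. The log2 ratio of Alk was 0.20 in the Xist set and 1.11 in the Y-linked set.

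The other named genes with a higher ratio in excitatory-like neurons were Sass6 (1.75), Grhl1 (1.68), Armc3 (1.68), Pstpip2 (1.64), Phldb2 (1.58), the class I antigen gene H2-T22 (1.57), Tmem181a (1.52), the cGMP-dependent kinase gene Prkg2 (1.52) and Pappa2 (1.52, 1.01 to 2.30). Those with a lower ratio were the co-chaperone gene Dnajc9 (0.442), the GABA receptor subunit gene Gabrq (0.492), Enho (0.495), Rplp0 (0.497), Nup210l (0.501), Arxes2 (0.504), Maf1, a repressor of RNA polymerase III (0.506), the splicing factor gene Syf2 (0.507) and the acid sphingomyelinase gene Smpd1 (0.508). Pstpip2 had only 2 naive UMIs in the Y-linked set. The 12 lower genes were 1.53 to 17.4 kb long, except Heph at 119.1 and Nup210l at 107.9 kb, and the 12 higher ones 36.0 to 735.7 kb, except H2-T22 at 5.62 kb. Over 10987 genes the median log2 ratio was -0.08, with an SD of 0.218 against 0.157 from counting error alone. Pearson r between the Xist and Y-linked sets, which share their libraries, was 0.331 across 6275 genes.

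The lists with lower levels in the injured library in excitatory-like neurons were ribosomal proteins, heat shock, immediate early genes, oxidative phosphorylation and neuropeptides. Ribosomal proteins had a median log2 ratio of -0.43 (percentile 0; 73 of 77 under 1), with Rpl24 at 0.556 (0.459 to 0.672). Heat shock genes had -0.39 (percentile 0; 9 of 10 under 1), immediate early genes -0.58 (0.02; 11 of 14) and oxidative phosphorylation -0.28 (percentile 0; 40 of 45). Neuropeptides had -0.50 (percentile 0; 17 of 19), led by Gal and by Pnoc, the nociceptin precursor, at 0.525 (0.355 to 0.768). Gal and Pnoc are not separated from free RNA in this class, and Npy, Cartpt and Nppc were at 3.17, 4.81 and 3.67 CPM in its naive nuclei against 15.7, 37.4 and 15.4 CPM in inhibitory-like ones, so the list median can partly follow free RNA of inhibitory-like nuclei. GABA and glycine receptors had 0.12 (percentile 99.97; 17 of 19 over 1), with Gabrb2 at 1.35 (1.18 to 1.54) and the glycine receptor gene Glra3 at 1.30 (1.16 to 1.45). Ionotropic glutamate receptors had 0.11 (percentile 98.3), but lay within the middle of random lists under 11 of 14 alternatives, at percentile 54.3 in the Y-linked set, with Grik2 at 1.19 (1.14 to 1.24).

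The other functional lists in excitatory-like neurons lay within the middle of random lists at the main setting: neuropeptide receptors -0.20 (percentile 10.7), metabotropic glutamate receptors 0.05 (67.7), sodium channels 0.02 (45.6), potassium and HCN channels 0.02 (77.1), calcium channels 0.00 (29.1), presynaptic release 0.03 (74.7), postsynaptic scaffolds 0.05 (96.9), axon guidance 0.07 (92.3), neuronal adhesion 0.10 (95.6), neurotrophin signalling and axon regeneration -0.05 (38.9), chromatin and DNA methylation -0.02 (70.5), inflammatory signalling -0.20 (7.56), mitochondrially encoded genes -0.10 (65.5) and Y-linked genes 0.05 (94.1). Markers of other cells had medians of -0.73 for astrocytes (percentile 0.07, on 4 genes), 0.00 for oligodendrocytes (83.1), 0.22 for their precursors (99.4), -0.01 for microglia (79.2), -0.41 for endothelial cells (6.44), -0.17 for mural cells (43.1) and 0.33 for ependymal cells (89.9). Fewer than 3 genes of the Schwann cell, fibroblast, lymphocyte and X-inactivation lists were measured.

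**Figure D2:**
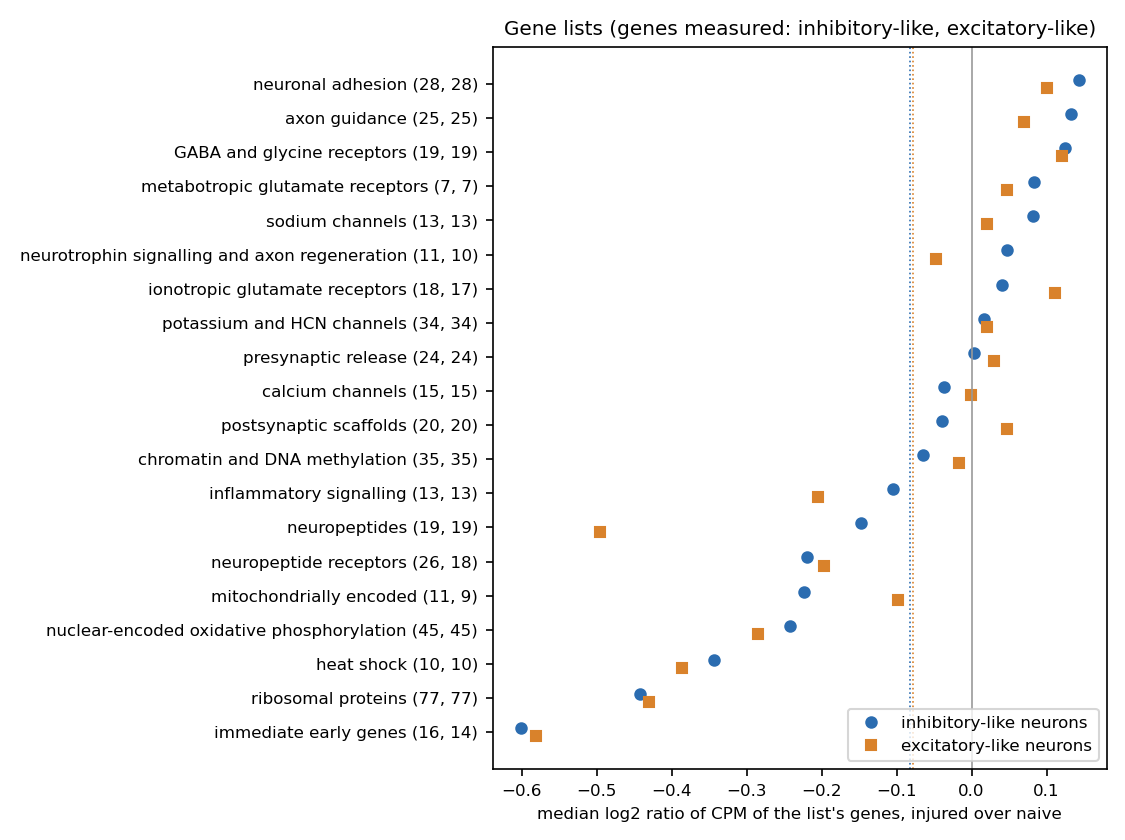
Median log2 ratio of CPM, injured over naive (x axis), of the 20 functional gene lists in inhibitory-like (circles) and excitatory-like neurons (squares), with the number of genes measured in each class. Dotted lines mark the median of all genes of a class, -0.08 in both; ribosomal proteins lie at -0.44 and -0.43.

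The log2 ratios of inhibitory-like and excitatory-like neurons ran together: the Pearson coefficient was 0.473 and the Spearman coefficient 0.468 across 10858 genes with at least 100 UMIs in each class. At a minimum of 500 UMIs the Pearson coefficient was 0.665. Genes are not independent replicates, and both classes of a library share its preparation and its free RNA.

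Pdyn itself, the gene that marks the lineage, had ratios between libraries and between neuron classes with counting intervals that held 1 over all nuclei. Without cluster 23, a setting chosen after seeing the data, Pdyn was lower in injured inhibitory-like neurons (log2 ratio -0.33). In the Xist set it was lower in the injured library, which in inhibitory-like neurons depends on the scaling. In inhibitory-like neurons Pdyn (ENSMUSG00000027400, chromosome 2, 129686565 to 129699844) was at 37.2 CPM (34.4 to 40.1) in the naive and 35.0 CPM (32.4 to 37.8) in the injured library, a ratio of 0.943 (0.845 to 1.05). In excitatory-like neurons it was at 41.2 CPM (36.8 to 45.9) and 37.0 CPM (33.0 to 41.4), a ratio of 0.90 (0.77 to 1.05). Inhibitory-like neurons held 678 of 1028 naive Pdyn UMIs (65.9%, 63.0 to 68.8) and 651 of 1014 injured ones (64.2%, 61.2 to 67.2). Without cluster 23 the log2 ratio of Pdyn in inhibitory-like neurons was -0.33, against -0.09 with it. In the Xist set the ratio was 0.846 (0.729 to 0.982) in inhibitory-like and 0.754 (0.607 to 0.936) in excitatory-like neurons. In the Y-linked set it was 0.986 (0.825 to 1.18) and 1.23 (0.921 to 1.64). With the shift of log2 ratios under other ways of scaling, the inhibitory-like interval in the Xist set would hold 1. Pdyn is 13.3 kb long, and genes of 9.73 to 20.8 kb had a median log2 ratio of -0.14 in inhibitory-like neurons. Its ratios are not corrected for length.

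Pdyn levels differed far more between clusters than between libraries, although Pdyn and the other peptides were held out of the clustering. Cluster 23 had the highest level, 201.2 CPM (142.4 to 276.2) in the naive and 288.6 CPM (243.1 to 340.1) in the injured library, and Pdyn is 1 of its 10 leading genes. Among larger inhibitory-like clusters, cluster 1 had 91.2 and 78.9 CPM and cluster 7 had 72.8 and 44.1 CPM. In the largest excitatory-like cluster, number 4, Pdyn was at 53.9 and 63.6 CPM. CSF-contacting-like neurons had 2 Pdyn UMIs in each library. A Pdyn UMI was found in 20.9% of naive and 20.4% of injured inhibitory-like nuclei (median depths 6683 and 7853 UMIs). After thinning to 4000 UMIs these shares were 13.9% and 12.1%. Oligodendrocyte-like nuclei, which should lack the gene, gave 0 of 42 and 0 of 45 nuclei at median depths of 2146 and 2593 UMIs. Nuclei so few and shallow do not show that free Pdyn RNA is negligible.

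**Figure D3:**
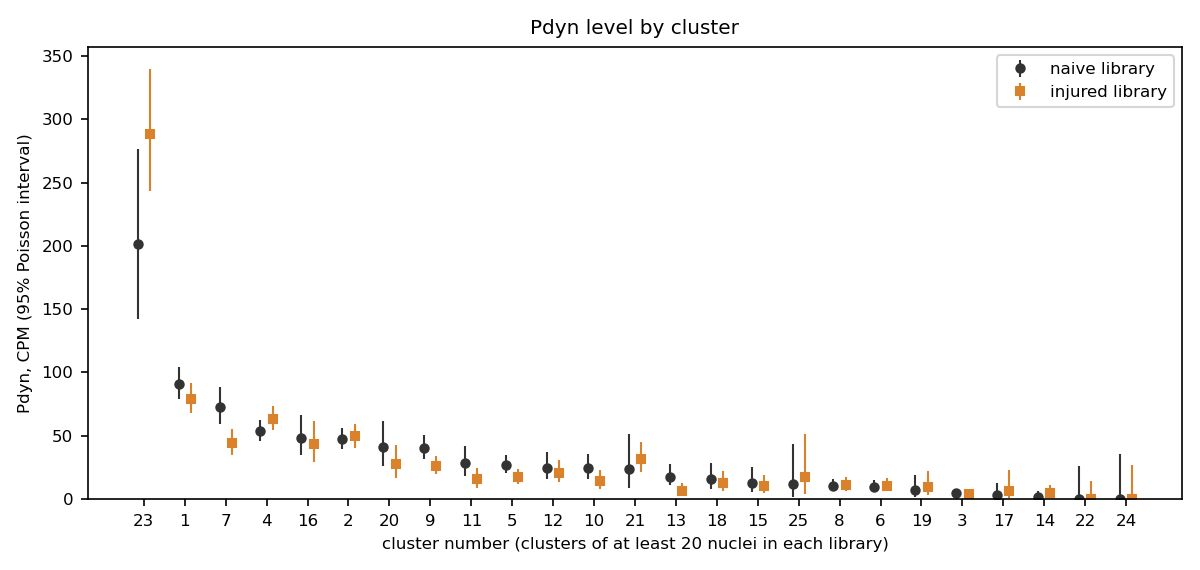
Pdyn level in CPM (y axis) with 95% Poisson intervals in each cluster of at least 20 nuclei per library, naive (circles) and injured (squares), ordered by the naive level. Cluster 23 lies at 201.2 and 288.6 CPM.

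Several other peptides were divided between the neuron classes in the same order in both libraries, while Nmb, the neuromedin B gene, was at 1.01 times (0.616 to 1.61) its inhibitory-like level in excitatory-like neurons of the naive and 0.534 times (0.275 to 0.968) in those of the injured library. Penk, the enkephalin precursor, was 2.88 times (2.66 to 3.11) as high in excitatory-like as in inhibitory-like neurons of the naive library and 2.99 times (2.73 to 3.28) in the injured. Tac1, the precursor of substance P, was 12 times and 11 times as high, and Cck 6.06 and 4.63 times. Adcyap1, the precursor of the peptide PACAP, was at 40.4 CPM in naive and 28.9 CPM in injured excitatory-like neurons, against 1.15 and 0.323 CPM in inhibitory-like neurons. Galanin and nociceptin precursors went the other way, with Gal at 0.18 (0.15 to 0.20) and 0.13 (0.10 to 0.15) and Pnoc at 0.0872 and 0.0627 times the inhibitory-like level; neither excitatory-like level is separated from free RNA (Pnoc 10.1 CPM in naive excitatory-like neurons, against 19.2 CPM, 2.33 to 69.4, in naive oligodendrocyte-like nuclei). The mu opioid receptor gene Oprm1 was at near-equal levels (ratios 0.958, 0.889 to 1.03, and 0.985, 0.915 to 1.06). The kappa receptor gene Oprk1, which encodes the receptor for dynorphin, was highest in CSF-contacting-like neurons, at 134.9 CPM (106.3 to 168.9) and 116.2 CPM (81.8 to 160.2), against 24.8 and 20.6 CPM in inhibitory-like neurons.

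Between libraries, most of these peptides had ratios under 1 in both classes, though some levels are not separated from free RNA of the other class. Gal had ratios of 0.660 in inhibitory-like and 0.474 in excitatory-like neurons, Penk 0.663 and 0.690, Pnoc 0.731 and 0.525, Tac1 0.629 and 0.585, and Sst, the somatostatin gene, 0.504 and 0.677. The excitatory-like ratios of Gal and Pnoc can follow free RNA of inhibitory-like nuclei. In inhibitory-like neurons Tac1 was at 7.01 and 4.41 CPM, against 84.4 and 49.4 CPM in excitatory-like ones. Sst was at 5.97 and 3.01 CPM, against 13.05 and 8.835 CPM. Whether these lower levels follow free RNA was not tested. Among random lists matched on gene length and expression, the neuropeptide list lay at percentile 73.3 in inhibitory-like and 0.01 in excitatory-like neurons, at the main setting; the lower inhibitory-like medians under other settings were not matched on length. Nts, the neurotensin gene, was at 1.99 (1.19 to 3.43) in excitatory-like neurons, on 23 naive and 48 injured UMIs. Nts leads the genes of a small part of cluster 15 with 8 naive and 14 injured nuclei. Its ratio is therefore not separated from the share of those few nuclei. Oprm1 had ratios of 0.949 and 0.976, and Oprk1 0.832 and 0.729. A Gal UMI was also found in 14.3% of naive and 11.1% of injured oligodendrocyte-like nuclei, against 57.3% and 49.3% of inhibitory-like and 21.2% and 13.2% of excitatory-like nuclei, the latter at median depths of 8112 and 9957 UMIs.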

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

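The tests of cluster 21, of tissue near the central canal, and of cluster 23 as the whole source of Alk in excitatory-like neurons were chosen only after the result was seen. The matching on gene length was made finer after its first results had been seen.

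Ribosomal protein, heat shock, immediate early and oxidative phosphorylation transcripts were lower, and GABA and glycine receptor and neuronal adhesion transcripts higher, in the injured library, along a trend in which longer genes had higher ratios (Pearson r 0.475 across 12354 genes in inhibitory-like neurons, genes not being independent replicates). Gene length alone is argued against for most of these lists: among random lists matched on length and expression, percentiles in inhibitory-like and excitatory-like neurons were 0 and 0 for ribosomal proteins, 0.33 and 0.18 for heat shock, 0 and 0.08 for immediate early genes, and 99.96 and 99.69 for GABA and glycine receptors. Length cannot be told apart from another cause for oxidative phosphorylation (3.1 and 0.07) and neuronal adhesion (97.61 and 41.06), where the classes lie on different sides of the limit. Axon guidance, placed in the same way, lay at 98.65 and 49.2, and presynaptic release at 44.49 and 61.83. RNA quality or handling shared by all nuclei of a library stays open. The summed CPM of ribosomal proteins was also lower in injured oligodendrocyte-like and astrocyte-like nuclei (ratio 0.620, 0.560 to 0.687) than in naive ones, as in inhibitory-like (0.733) and excitatory-like neurons (0.739). Taken apart, the ratio was 0.757 (0.632 to 0.907) in oligodendrocyte-like and 0.547 (0.482 to 0.620) in astrocyte-like nuclei, whose sampling is in question below. In the same glia-like nuclei heat shock transcripts had a ratio of 0.547 (0.461 to 0.649), oxidative phosphorylation 0.824 (0.739 to 0.919) and mitochondrially encoded transcripts 0.596 (0.438 to 0.811). Immediate early transcripts had 0.861 (0.585 to 1.27) on 48 naive and 67 injured UMIs, an interval that holds both 1 and the inhibitory-like ratio of 0.696, with 1.57 (0.735 to 3.57) in oligodendrocyte-like and 0.647 (0.409 to 1.03) in astrocyte-like nuclei. For the receptor and adhesion lists shared handling was not tested. An effect of the incision on all these cells, which each pool shares with its preparation, was not tested.

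Some signals at the edges of classes may come from doublets. Cluster 21, with neuron and oligodendrocyte markers together, made up 0.566% of naive and 2.28% of injured nuclei, and 32.1% of its injured nuclei (22.2 to 43.4) had both Xist and Y-linked UMIs, against 4.29% (3.48 to 5.22) of injured inhibitory-like nuclei, which is consistent with doublets. For Alk in excitatory-like neurons, the summed level of Gad1, Gad2, Slc32a1, Slc6a5 and Cartpt in the 19 injured nuclei with at least 20 Alk UMIs was 81.57 CPM (51.7 to 122.4), above the 28.6 CPM (24.98 to 32.53) of the remaining nuclei, the outcome set beforehand for some RNA from cluster 23. As the whole source it is argued against: their Alk level would need 810.6 CPM of these genes at the ratio found in cluster 23, a criterion chosen after that value was seen. Without nuclei with both sex markers, a setting also chosen later, the log2 ratio of Alk in excitatory-like neurons was 0.50 in place of 0.61. Doublets of 1 sex marker stay in: among random pairs of this class, 38.7% (naive) and 40.6% (injured) would mix the markers. The value of 0.50 is therefore not one without doublets. A higher Alk level in a few excitatory-like neurons after the incision, or in the mice that gave these nuclei, stays open and was not tested.

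CSF-contacting-like nuclei differed in opposite directions by sex marker: 96 of 2654 naive and 29 of 2197 injured Xist nuclei (3.62% and 1.32%, ratio 0.3649), but 5 of 1054 and 16 of 1069 Y-linked nuclei (0.47% and 1.5%, ratio 3.155). Astrocyte-like nuclei, cluster 22, did likewise, with ratios of 0.5575 and 2.958. Neither difference between the sets was tested. Uneven sampling of tissue near the central canal between mice is a candidate explanation: the Xist part of cluster 22, which also carries ependymal markers, was 86.67% (73.2 to 94.9) in the naive and 50% (33 to 67) in the injured library, although these are the nuclei behind the astrocyte-like ratios. The Xist part also fell in neuron cluster 3, from 83.7% (78.9 to 87.8) to 71.0% (65.8 to 75.8), so such a fall is not particular to this tissue. A difference between the sexes in their response stays open and was not tested.

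In all, 30 shares and 227 gene ratios were compared between the sex-marker sets and 202 gene ratios between the neuron classes, without a test of the difference. The following, beside the shares above, went in opposite directions with both counting intervals clear of 1; other ratios on opposite sides of 1, where an interval held 1, are not listed. In inhibitory-like neurons, Cartpt had a ratio of 0.8036 in Xist and 1.255 in Y-linked nuclei, but cluster 23, most of whose nuclei had Y-linked UMIs, held 188 of the 682 naive and 466 of the 811 injured Cartpt UMIs, so a rise in the rest of the class is not shown. Over both sex-marker sets, Cartpt in that rest was lower in the injured library. It was at 26.1 and 17.5 CPM in nuclei with fewer than 20 Alk UMIs, and at 193.3 and 97.9 CPM in the 17 naive and 34 injured others. Cdh9 in that class had 0.8606 and 1.225. In excitatory-like neurons, Kirrel3 had 0.9392 in Xist and 1.124 in Y-linked nuclei. Between the classes, the endothelial gene Adgrl4 had a ratio of 2.314 in inhibitory-like and 0.6415 in excitatory-like neurons. The cadherin gene Cdh8 had 0.9765 and 1.235. Pappa2 had 0.708 in inhibitory-like and 1.515 in excitatory-like neurons, and Prkg2 had 0.8347 and 1.518. None of these differences was tested. With the 0.08 or so that other ways of scaling add to log2 ratios, Cdh8 would lie above 1 in both classes, and the intervals of Cartpt, Cdh9 and Kirrel3 in Xist nuclei and of Pappa2 in inhibitory-like neurons would hold 1, so their opposite directions depend on the scaling.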

How the results depend on the processing

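Adding unnamed neuron clusters, leaving out nuclei with both sex markers and leaving out cluster 23 were chosen after seeing the data. Of 103 comparisons of the main values with an alternative, 88 stayed within the counting interval or limit of change and 15 did not. From each nucleus's own markers, the inhibitory-like share was 63.9% in the injured library, and the excitatory-like shares 17.5% (naive) and 19.0% (injured). With 1000 variable genes and 20 components the excitatory-like shares were 19.94% and 20.02%. The correlation of log2 ratios between classes was 0.665 at a minimum of 500 UMIs. The SD of log2 ratios was 0.317 in inhibitory-like and 0.330 in excitatory-like neurons at a minimum of 20 UMIs, 0.0394 and 0.0492 from the authors' normalized values, whose log compresses low levels, and 0.325 and 0.390 in Y-linked nuclei. The log2 ratio of Pdyn was -0.33 in inhibitory-like neurons without cluster 23, and -0.41 (Xist nuclei) and 0.29 (Y-linked nuclei, with a counting interval that holds 0) in excitatory-like neurons. The cause was not tested for these values, except that fewer counts per gene widen the SD at a lower minimum. The oligodendrocyte marker median in inhibitory-like neurons, 0.15, was reversed in Y-linked nuclei (-0.11) and at minimums of 100 (-0.0095) and 500 UMIs (-0.033). The endothelial median, 1.21, was reversed in Y-linked nuclei (-0.13) and at a minimum of 100 UMIs (-0.39), which leaves out low genes but keeps Mecom. The cause in Y-linked nuclei was not tested.

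For single genes, lists and peptide ratios, 1256 comparisons stayed within their limits, 165 moved beyond them in the same direction or without a call, and 5 reversed, those given above. No named gene reversed under the alternatives of scaling, weighting, thinning and removal of nuclei, nor under the normalized values, where 47 of 48 moved. In the sets with Xist or Y-linked UMIs alone the naming rule itself fixed the direction, and only the sizes could move: 21 of 48 named ratios did in Y-linked nuclei, and 8 in Xist nuclei. The ribosomal, oxidative phosphorylation, GABA and glycine receptor and adhesion lists of inhibitory-like neurons stayed on the same side of random lists under all 15 alternatives run for each. So did the heat shock and immediate early lists of inhibitory-like and the ribosomal, oxidative phosphorylation and neuropeptide lists of excitatory-like neurons, under all that were run. Neuropeptide receptors in inhibitory-like neurons stayed outside under 7 of 15 alternatives, with percentiles of 25.77 in Y-linked nuclei, 22.18 at a minimum of 100 UMIs and 6.3 with nuclei weighing the same. Ionotropic glutamate receptors in excitatory-like neurons stayed outside under 3 of 14, with 54.28 in Y-linked nuclei, 81.81 with clusters weighing the same and 86.22 without Scrublet doublets. Axon guidance in inhibitory-like neurons and the GABA and glycine receptor, heat shock and immediate early lists in excitatory-like neurons each moved under 1 alternative. Of the marker lists, astrocyte in excitatory-like and precursor in both classes moved under 2 alternatives each. Neuropeptides in inhibitory-like neurons, within the middle at percentile 18.12, fell below 2.5 under 5 alternatives chosen beforehand and without cluster 23. Other lists within the middle at the main setting also left it under some alternatives, so their place there is not fixed. The TMM and median-of-ratios factors raised log2 ratios by about 0.08. Minimums of UMIs were not applied to named genes, which have at least 100. Y-linked genes gave no value in Xist nuclei by construction. Counts of genes by size of the ratio, foreseen as a result, were not made, since 1 library per group gives them no error; the SD stands in their place. No paired analysis was possible because each group is 1 pool of mice. Depth limits genes with few UMIs: a count of 0 in inhibitory-like neurons allows up to 0.164 CPM (naive) and 0.161 CPM (injured), in excitatory-like neurons 0.380 and 0.363 CPM.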

Other observations

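The comparisons by sex marker below were chosen only after the data were seen. Alk was higher in inhibitory-like nuclei with Y-linked UMIs than in those with Xist UMIs, in both libraries. In the naive library it was at 203.4 CPM (195.2 to 211.9) in Xist and 492.8 CPM (474.1 to 512) in Y-linked nuclei, a ratio of 2.42 (2.29 to 2.56). In the injured library it was at 274.8 CPM (265.3 to 284.6) and 1017 CPM (991.6 to 1044), a ratio of 3.70 (3.55 to 3.87). Cluster 23, the high-Alk inhibitory-like cluster, made up 22 of 1054 naive (2.09%) and 52 of 1069 injured Y-linked nuclei (4.86%), against 5 of 2654 (0.188%) and 4 of 2197 (0.182%) Xist nuclei. These shares are set against each other between the sets of a library, not between libraries, since Alk helps to define the cluster. Without it the Y-linked over Xist ratio of Alk was 1.48 (1.39 to 1.58) in the naive and 1.35 (1.28 to 1.44) in the injured library. In excitatory-like neurons the ratio was 0.979 (0.878 to 1.09) and 1.84 (1.70 to 1.99). The number of mice of each sex in a pool is not given in the sources used here, so sexes and single mice were not separated.

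Cluster 23 also stood out for its peptides, which were held out of the clustering. Cartpt, the precursor of the CART peptides, was at 995.6 CPM in the naive and 947.0 CPM in the injured library, and Gal at 619.6 and 333.3 CPM. Other genes of inhibitory-like neurons had the opposite relation to the sex markers: Fam19a2 was lower in Y-linked than in Xist nuclei, with ratios of 0.519 (0.410 to 0.652) in the naive and 0.667 (0.570 to 0.778) in the injured library, as was Zfpm2, with 0.695 (0.506 to 0.942) and 0.571 (0.453 to 0.714). Fam19a2 and Zfpm2 are leading genes of parts of cluster 3, some of them unnamed, and the naive nuclei of cluster 3 had a higher Xist part (83.7%) than those of inhibitory-like neurons (68.4%), so cluster make-up is not separated from the sex markers here. Ribosomal transcripts, summed, were also lower in injured CSF-contacting-like neurons (ratio 0.711, 0.647 to 0.779), on 106 naive and 48 injured nuclei.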
